A study of Mus musculus with 2 samples.

How the data were processed

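Single-cell RNA was measured in CD45+ cells sorted from hearts of sham-operated mice and of mice with transverse aortic constriction (TAC). Each group is 1 library of cells from 6 mice, and the animals cannot be told apart within a library. The deposited matrices hold raw counts of unique molecular identifiers (UMIs) per gene and barcode, with no normalisation. The authors made them with Cell Ranger 3.0 against mm10, per the submitters' processing notes, and list 31053 features. How barcodes were called as cells is not given in the sources used here. The labels describe libraries from several GEM wells (droplet runs), but every barcode carries the suffix 1, so runs could not be separated. Gene positions come from GENCODE vM21 on GRCm38, the assembly that mm10 names.

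Barcodes with at least 300 detected genes and at most 10% mitochondrial UMIs were kept, which left 4169 of 11941 sham and 5601 of 7975 TAC barcodes. Before the filter, 1503 sham and 535 TAC barcodes had under 300 genes, and 7590 and 2246 had over 10% mitochondrial UMIs. Scrublet, run per library in scanpy, called 0 sham and 4 TAC barcodes doublets. At that number it has not worked on these data, so doublets are in effect not removed. Kept cells were 4169 and 5597, with 50738794 and 90264952 UMIs, median depths of 9536 and 13891 UMIs, and median mitochondrial shares of 8.02% and 4.42%. Both libraries were clustered together without integration, on 2000 variable genes, 30 principal components, 15 neighbours and the Leiden algorithm at resolution 1. Software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.

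Clusters were named in 2 steps from marker lists fixed before the data were examined, as were 25 gene lists, the comparisons and the rule for naming genes. A cluster took the name of the class with at least 3 markers among its 10 leading genes and more than any other class. Each remaining cluster took the class with the highest share of its markers detected in at least 50% of the cluster's cells, if that share was at least 55% and no other class had both more markers among the 10 leading genes and more than 2. That second step is the last of 4 versions, and each change was made after names had been seen. The first counted markers among 30 leading genes and was dropped because names went against the leading genes and C1q. The second took the nearest class by correlation, with r of at least 0.9, and gave unstable names. The third set the share at 50% and passed clusters 15 and 20 narrowly, both at 51.0%, as macrophages. Those clusters stay unnamed, with 177 sham and 95 TAC cells. The macrophage clusters 1, 5, 11, 12 and 18 were named in the second step, at 59.2%, 65.3%, 69.4%, 75.5% and 77.6%. Earlier versions gave other names to cluster 1 (dendritic cell by correlation), cluster 5 (dendritic cell by 30 genes), cluster 11 (monocyte by correlation, unnamed by 30 genes), cluster 15 (macrophage by 30 genes) and cluster 18 (unnamed by 30 genes). Names mean "like" the class in markers and do not establish identity.

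With 1 library per group no test across samples can be made, and cells are not replicates. Shares of kept cells carry exact Clopper-Pearson 95% intervals. For gene values, UMIs were summed over the cells of a class and given as CPM, UMIs scaled to a common class total, with exact Poisson intervals, in the 5 classes with at least 100 cells in each library. Class totals were 26583436 and 43812634 UMIs in macrophages, 2079087 and 14609925 in neutrophils, 2453714 and 6838671 in T cells, 2127767 and 4327924 in fibroblasts, and 1210650 and 3944214 in endothelial cells. Folds from 0 counts are lower bounds against a floor of 3 counts in the class of that library.

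Gene lists were summarised by the median log2 ratio over members with at least 20 UMIs over both libraries, with 0.5 UMI added to each count, with a distribution-free interval over members, and by its percentile among 10000 random lists of like expression. Members past 1.5-fold are counted in each direction. The lists named in the text were fixed, except the ribosomal protein and mitochondrial genome lists, which were added later. Genes were named by rule in the 4 compared classes with most cells in the smaller library. These were the 10 genes with the highest and the 10 with the lowest ratio among genes with at least 50 CPM in either library and 50 UMIs over both. Mitochondrial, ribosomal, haemoglobin, receptor segment, sex-linked and predicted genes and markers of other classes only were left out. Up to 2 of the highest and 2 of the lowest members of each list described were named too. S100a8, Ptprc, Cd3e and the C1q genes were chosen after their values were seen.

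Shares of cells with a UMI of a gene were taken after thinning each cell to 1000 UMIs, with 1 shallower macrophage left out per library and 0 cells in other classes. Fibroblasts served as the background. They carried less macrophage RNA than lymphocytes and neutrophils, so they do not show the level that macrophage RNA adds. An upper limit beside a share of 0 is 3 counts of the cells. C1q-rich barcodes are those with over 20 UMIs of C1qa, C1qb and C1qc per 10000, a limit set after the data were seen. Where they were left out, they were taken out of the named classes other than macrophages. All macrophages and unnamed cells stayed in the denominator.

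Alternatives fixed in advance were a filter of 500 genes and 5% mitochondrial UMIs, doublets kept, resolution 2, each library clustered alone, immune classes as the denominator, median-of-ratios scaling, mean CPM per cell, thinning, member minimums of 5 and 100 UMIs, and 2 UMIs added. A mitochondrial limit of 25%, leaving out C1q-rich barcodes, and the earlier naming rules were added after seeing the data. So was the choice of which lists to follow in which class under the alternatives.

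The counting intervals were tested on simulated data with no biological spread. In simulated macrophages they covered 97% of 2-fold and 95% of 4-fold differences, and in simulated fibroblasts 96% and 98%.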

Results

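The data were single-cell transcriptomes of leukocytes sorted from mouse hearts. Hearts of wild-type C57BL/6 mice aged 10 weeks were digested, cells carrying the pan-leukocyte surface protein CD45 were sorted by flow cytometry, and single-cell libraries were made in droplets on the 10x Genomics platform. Transverse aortic constriction (TAC) narrows the aorta and makes the left ventricle pump against a raised pressure, and sham animals have the operation without the constriction. Each group is 1 library, described by the submitters as coming from 6 mice per group. The question the design addresses is how the leukocytes of the pressure-overloaded heart differ from those of the sham heart. The sham library held 11941 barcodes and 87532984 unique molecular identifiers (UMIs), with a median of 6280 UMIs and 1798 genes per barcode. The TAC library held 7975 barcodes and 97983083 UMIs, with a median of 9781 UMIs and 2390 genes. With 1 library per group, nothing separates the library from the condition, no difference has a replicate check, and no p-value is given. Intervals of shares and of gene ratios are 95% intervals that cover counting error only, and intervals of list medians cover the spread over member genes.

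Neutrophils and monocytes made up larger shares of the TAC library, and macrophages, B cells and the cluster named as conventional dendritic cells smaller ones. Neutrophil-like cells, the granulocytes that enter injured tissue early, were 4.17% of kept sham cells (174 cells, Clopper-Pearson interval 3.59 to 4.83) and 20.9% of kept TAC cells (1170 cells, 19.8 to 22.0), a 5.01-fold higher share (4.27 to 5.91). Monocyte-like cells were 1.61% (1.25 to 2.04) in sham and 6.31% (5.68 to 6.98) in TAC, 3.92-fold higher. Macrophage-like cells were 65.7% (64.2 to 67.1) of sham and 48.8% (47.5 to 50.2) of TAC cells. B-like cells were 3.79% in sham and 0.983% in TAC, 3.86-fold lower. The cluster named as conventional dendritic cells was 6.26% and 1.38%, 4.55-fold lower, but its leading genes were Mmp12 and Cd209a, and finer clustering (resolution 2) put 40 sham and 40 TAC cells in a cluster with the dendritic genes Xcr1 and Clec9a. A cluster with Mmp12, Cd209a and Fn1 held 186 sham and 19 TAC cells there and met no class name. The cluster with Xcr1 and Clec9a was 0.959% of sham and 0.715% of TAC cells, 1.34-fold lower.

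T-like cells were 3.65% of the sham and 5.29% of the TAC cells, 1.45-fold higher (1.19 to 1.78). NK-like cells were 1.27% and 1.32%, a difference within the counting intervals. Cells without leukocyte markers also passed the sort: endothelial-like cells were 2.85% in sham and 7.65% in TAC, 2.68-fold higher, and fibroblast-like cells 5.11% and 4.43%. Ptprc, which encodes CD45, was detected in 22.5% of cells of the endothelial cluster and 17.6% of the fibroblast cluster. Clusters led by cardiomyocyte genes (29 sham and 29 TAC cells), haemoglobin genes (24 and 24) and platelet genes (5 and 14) were small. The cardiomyocyte-marker cluster carried C1q at a median of 145 UMIs per 10000 in sham, close to the 169 of macrophages, and Ptprc in 91.4% of its cells. Clusters 15 and 20, left without a name by a limit set after the data were seen, held 177 sham cells (4.25%) and 95 TAC cells (1.70%).

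The share of barcodes that passed the cell filter was 34.9% in sham and 70.2% in TAC, because 7590 sham and 2246 TAC barcodes had over 10% mitochondrial UMIs, and every share is conditional on that filter. The neutrophil share stayed higher in TAC under all the alternatives tried, from 4.64-fold to 32.9-fold, the latter with 15 sham cells left. The endothelial share stayed higher too, from 1.26-fold at a mitochondrial limit of 25% to 3.81-fold. With at least 500 genes and at most 5% mitochondrial UMIs together, which left 119 sham cells, the log2 ratio of the share turned to 0.28 for macrophages and −0.49 for T cells. Monocytes went to −0.87 with each library clustered alone, where a sham cluster of 402 cells led by Mmp12 and Fn1 took that name, and dendritic cells to −0.10 in that setting and 1.62 under an earlier naming rule. B cells went to 2.55 when barcodes rich in the macrophage transcripts of C1q were left out of the named classes other than macrophages. That value rests on 2 sham and 16 TAC cells, with all macrophages still counted in the total.

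**Figure D1:**
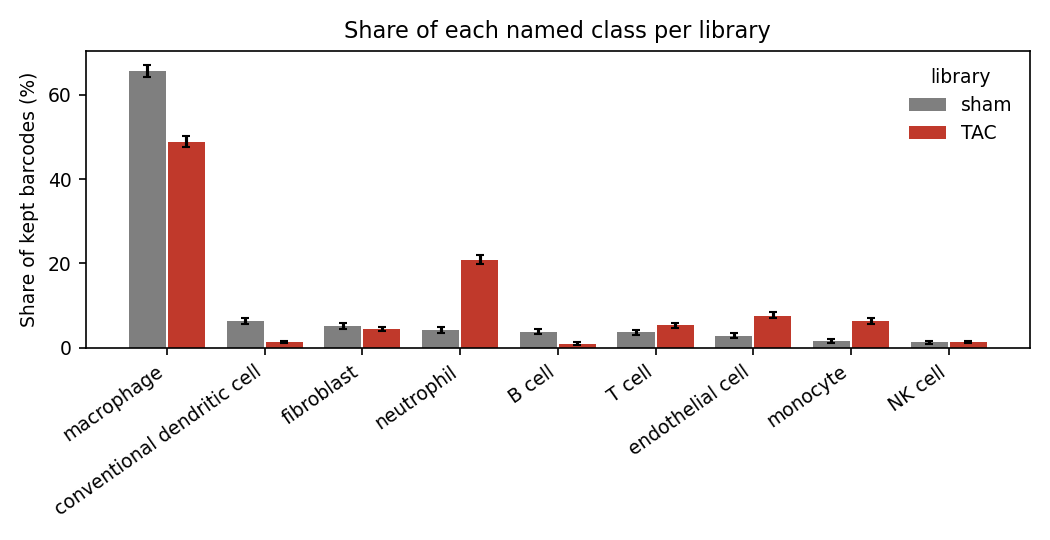
Share of kept cells in each class, in percent, for the sham library and the TAC library, with exact Clopper-Pearson 95% intervals as error bars. Neutrophils stand at 4.17% and 20.9%, and macrophages at 65.7% and 48.8%.

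Within macrophage-like cells, interferon-inducible genes were higher and genes of resident macrophages and heat-shock proteins lower in the TAC library. Saa3, an acute-phase apolipoprotein, was at 0.715 UMIs scaled to a common class total (CPM) in sham and 325 CPM in TAC, 455-fold higher (291 to 756). Interferon-inducible guanylate-binding proteins followed, with Gbp8 111-fold, Gbp4 94.4-fold, Gbp2b 93.0-fold and Gbp2 30.4-fold (27.9 to 33.1) higher. Ly6a, the interferon-inducible surface antigen Sca-1, was 74.9-fold higher (68.5 to 82.2). Lower in TAC were Cd209f, a C-type lectin, 29.6-fold (24.2 to 36.6), Retnla, a secreted product of alternatively activated macrophages, 18.4-fold (17.7 to 19.1), and Ccl24, an eosinophil chemokine, 16.9-fold.

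The other genes with the highest ratios were Fam26f (29.97-fold), Il18bp, the secreted inhibitor of interleukin-18 (27.1-fold), Cxcl9, an interferon-gamma-inducible T cell chemokine (23.9-fold), and Cd274, which encodes the inhibitory ligand PD-L1 (20.5-fold). The other genes with the lowest ratios were the chaperone genes Hspa1b (12.1-fold lower), Hspa1a (7.35-fold), Dnajb1 (6.86-fold) and Hspb1 (6.27-fold), the phospholipase gene Pla2g2d (8.08-fold), Fam71a (5.61-fold) and Chp2 (4.75-fold). Saa3 (ENSMUSG00000040026) lies on chromosome 7 at 46711998 to 46715700, Ly6a (ENSMUSG00000075602) on chromosome 15 at 74994877 to 74998031, Retnla (ENSMUSG00000061100) on chromosome 16 at 48842551 to 48844461 and Cd209f (ENSMUSG00000051906) on chromosome 8 at 4102787 to 4105835, all in mm10 and annotated as protein coding. Gbp2b (142594847 to 142619179) and Gbp2 (142620602 to 142638008) are neighbours on chromosome 3. Gbp4 (105115767 to 105139586) and Gbp8 (105014150 to 105139540) overlap on the minus strand of chromosome 5. Values of single Gbp genes, and those of the near-identical Hspa1a and Hspa1b, are uncertain, since reads may not be assigned to the right copy.

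Of 33 measured interferon-stimulated genes, 31 were at least 1.5-fold higher in TAC macrophages and 0 lower, with a median log2 ratio of 1.69 (over members, 1.32 to 2.49). Ifi44 was 19.98-fold higher and Parp14 1.30-fold. That median stood at percentile 100 of 10000 random lists matched on expression, as a description of these libraries. Of 14 genes of MHC class II presentation, which display peptides to CD4 T cells, 11 were higher and 0 lower (median 1.11, percentile 100), with the lysosomal protease gene Ctss 3.01-fold and H2-DMb1 2.65-fold higher. Of 28 inflammatory cytokine and NF-kB target genes, 17 were higher and 2 lower (median 0.86), with Clec4e 5.01-fold and Ptgs2, the inducible cyclooxygenase, 3.79-fold higher and Il6 2.72-fold lower. Glycolysis and hypoxia genes had 16 of 26 higher and 1 lower (median 0.73), with Vegfa, an angiogenic factor, 9.94-fold higher. Oxidative phosphorylation genes were higher by less, with 6 of 44 past 1.5-fold and 0 lower (median 0.34, percentile 97.6).

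Of 22 tissue-resident macrophage genes, 21 were at least 1.5-fold lower in TAC macrophages and 0 higher (median −1.42, percentile 0). Cd209g was 59.0-fold lower (37.9 to 97.2), and Timd4, a phosphatidylserine receptor of self-renewing resident macrophages, 1.06-fold. Of 31 immediate-early and heat-shock genes, 23 were lower and 1 higher (median −0.94, percentile 0); Dusp2 was the higher member (2.58-fold). The 13 protein-coding genes of the mitochondrial genome had a median of −0.85 in the same cells, and ribosomal protein genes a median of 0.05. Cell cycle genes had 27 of 42 higher and 0 lower (median 0.77), with Aurka, a mitotic kinase, 2.97-fold higher. Fibrosis- and lipid-associated genes went both ways, 10 of 27 higher and 3 lower (median 0.07). Among them Arg1 was 30.9-fold higher (10.4 to 152, from 3 sham UMIs), Vegfa as above, and Igf1, a growth factor made by resident macrophages, 4.55-fold lower. Complement and scavenging genes had 3 of 20 higher and 4 lower (median −0.02), with the Fc receptor gene Fcgr1 3.05-fold higher and the cholesterol exporter gene Abca1 3.25-fold lower. The lower immediate-early and heat-shock genes were not particular to macrophages. That list was lower in all 5 compared classes, with medians from −0.55 in fibroblasts to −1.29 in T cells. In the unnamed cells Hspa1a was at 183 CPM in sham and 34.2 CPM in TAC. The cause of this shared difference was not tested.

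Markers of other cells also differed in these barcodes. Of 20 neutrophil granule genes, 16 were higher and 1 lower in TAC macrophages (median 4.20, or 3.51 with genes at 0 counts set to their bound), and 36 neutrophil markers, of which 32 were measured, had a median of 3.58. The neutrophil calprotectin gene S100a8 was at 47.6 CPM in sham and 736 CPM in TAC macrophages. Classical monocyte genes had a median of 2.56 (9 of 16 higher, 1 lower), with Ly6c2 27.8-fold and Chil3 26.4-fold higher. NK cell markers were higher in 16 of 19 (median 2.14), cytotoxic effector genes in 13 of 16 (2.002) and fibroblast markers in 22 of 36 (0.97). Non-classical monocyte genes had a median of 1.56 (9 of 17 higher, 2 lower), with Fcgr4 17.1-fold higher and Adgre4 7.52-fold lower.

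With every cell thinned to 1000 UMIs, Lyve1, a hyaluronan receptor of resident macrophages, was detected in 49.5% (47.6 to 51.4) of sham and 23.3% (21.7 to 24.9) of TAC macrophages. Folr2, a folate receptor of resident macrophages, was detected in 58.1% and 31.2%. Timd4 was detected in 11.7% and 9.66%, Trem2, a lipid-sensing receptor, in 17.1% and 16.2% (within the counting intervals), and Ccr2, the chemokine receptor of monocyte-derived cells, in 4.24% and 6.40%. Il1b was detected in 12.7% and 23.9%, against 3.30% and 6.48% in fibroblasts, which should lack it. Spp1, which encodes osteopontin, was detected in 0.841% and 5.20%, against 0% and 3.64% in fibroblasts, Mki67, a proliferation marker, in 3.62% and 4.90%, and Arg1 in 0 of 2736 sham macrophages, which allows up to 0.110%, and 0.256% of TAC macrophages. Such limits are 3 counts of the cells and cover cells with a UMI at that depth, not cells that express the gene. Background in fibroblasts was at most 4.25% for Lyve1, Folr2, Timd4, Trem2, Ccr2 and Mki67 in either library. Median depth was 8591 and 14196 UMIs in macrophages and 8921 and 15140 in fibroblasts. Unthinned shares were 80.6% and 45.2% for Lyve1, 89.5% and 69.2% for Folr2, 52.8% and 41.4% for Timd4, 65.8% and 66.8% for Trem2, and 13.6% and 25.6% for Ccr2. They were 28.6% and 56.7% for Il1b, 5.04% and 21.8% for Spp1, 9.17% and 21.8% for Mki67, and 0.110% and 1.61% for Arg1.

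Sham macrophages lay mostly in clusters 0, 3 and 5 and TAC macrophages in clusters 1, 2 and 11, so that sub-populations and libraries largely coincide. Under earlier naming rules the Saa3 log2 ratio of 8.79 went to 4.46, the cell cycle median to −1.40, the inflammatory median to 0.090 and the resident median to −0.67.

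**Figure D2:**
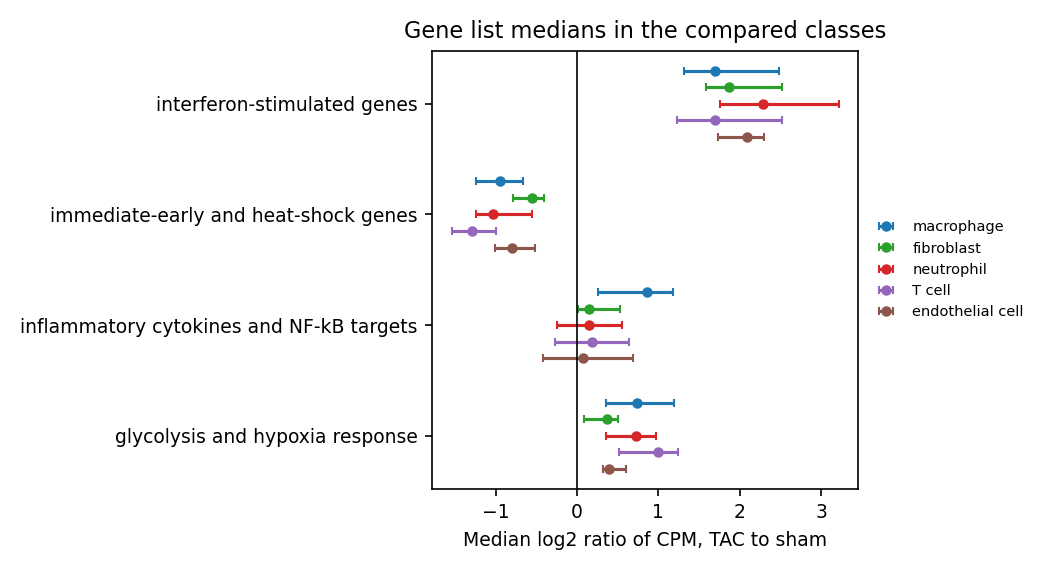
Median log2 ratio of TAC to sham CPM for gene lists in 5 cell classes, with the 95% interval of each median over its member genes as error bars. Interferon-stimulated genes lie between 1.69 and 2.28 in the 5 classes.

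Fibroblast-like cells also carried higher interferon-inducible genes in the TAC library, together with an injury-associated matrix gene. Gbp4 was 159-fold higher (43.9 to 1316, from 2 sham UMIs), Cxcl9 152-fold (from 2 sham UMIs) and Tgtp2, a GTPase of the interferon response, 113-fold (from 2 sham UMIs). Gbp10 had 0 sham UMIs and was at least 41.6-fold higher against a floor of 3 counts in the sham class. The GTPase genes Iigp1 (65.0-fold) and Igtp (54.1-fold), Serpina3f (48.2-fold), Ddah1 (29.3-fold) and Fam26f (28.8-fold) were also higher. Cthrc1, a secreted protein of activated fibroblasts, was at 2.35 CPM in sham and 170 CPM in TAC, 72.4-fold higher (30.9 to 224); it lies on chromosome 15 at 39076932 to 39087121.

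Ccl11, which encodes the chemokine eotaxin, was 29.8-fold lower in TAC fibroblasts (18.2 to 52.0). Cytl1 was 10.1-fold lower, the collagen gene Col6a6 7.92-fold, Fxyd2 5.89-fold, Hspa1a 5.24-fold, Ces1d 5.09-fold, the matrix gene Efemp1 4.66-fold, Penk 4.62-fold, Enpp2, which encodes autotaxin, 4.60-fold and Hspa1b 4.24-fold. Of 33 interferon-stimulated genes, 30 were higher and 0 lower (median 1.87, percentile 100), and of 31 immediate-early and heat-shock genes 15 were lower and 0 higher (median −0.55). Growth factor genes had 5 of 17 higher and 3 lower (median 0.20), with Ereg, an epidermal growth factor receptor ligand, 19.7-fold higher and Bmp2 5.77-fold lower. Of 12 neutrophil granule genes 11 were lower and 0 higher (median −1.52), among them Camp (75.3-fold) and Ltf (53.6-fold). Resident macrophage genes were lower in 19 of 20 (median −2.22), markers of macrophages had a median of −0.92 and mitochondrial genome genes −1.04, and C1q-rich barcodes were 13.6% of sham and 8.87% of TAC fibroblasts. With barcodes rich in C1q left out, the inflammatory median of 0.14 went to 0.87, Cxcl9 from a log2 ratio of 6.93 to 5.27 and Fxyd2 from −2.55 to −0.92.

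Endothelial-like cells had the same list higher. Of 33 interferon-stimulated genes, 32 were at least 1.5-fold higher in TAC and 0 lower (median 2.09, percentile 100), with Gbp2 25.7-fold and Zbp1, a nucleic acid sensor, 18.7-fold higher. Il6 was 13.01-fold higher (5.49 to 40.5) within an inflammatory list whose median was 0.07. MHC class II genes had a median of 0.24, which went to −0.42 with cells thinned to 1000 UMIs, and Ciita, their master regulator, was 3.39-fold higher. Immediate-early and heat-shock genes had 21 of 31 lower and 1 higher (median −0.79). Npr3, the natriuretic peptide clearance receptor, was 23.8-fold lower (14.8 to 40.1). Markers of mural cells, which wrap vessels, had 17 of 21 higher and 0 lower in the same cluster (median 1.22). Resident macrophage genes were lower in 19 of 20 (median −1.82), markers of macrophages had a median of −1.21 and mitochondrial genome genes −0.56, and C1q-rich barcodes were 37.0% of sham and 8.41% of TAC endothelial cells. Finer clustering (resolution 2) split this class by library too, with 11 sham and 297 TAC cells in a cluster led by Ly6c1 and Gpihbp1, 88 and 82 in a cluster led by Fabp4 and Aqp1, and 16 and 26 in a cluster with Vwf and Npr3. It put 4 and 23 cells in a mural cluster led by Rgs5 and Acta2, so a different mix of vessel cells is not separated from differences within them.

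Neutrophil-like cells of the TAC library were higher in interferon-inducible and granule genes. Saa3 had 0 sham UMIs and was at least 110-fold higher, and Ifit1bl1 had 0 sham UMIs and was at least 38.1-fold higher. Gbp4 was 285-fold higher (51.1 to 11258, from 1 sham UMI), Gbp2b 147-fold (40.7 to 1218, from 2), Gbp8 43.7-fold (14.9 to 212, from 3), Gbp2 41.5-fold, Cxcl9 41.3-fold, Ly6a 37.4-fold, Tgtp2 32.2-fold and Ifit3b 28.9-fold. Of 33 interferon-stimulated genes, 32 were higher and 0 lower (median 2.28), and of 17 granule genes 13 were higher and 0 lower (median 2.04), with Chil3, a chitinase-like protein, 26.3-fold and Cd177 12.0-fold higher. Genes of aged and SiglecF neutrophils had 5 of 21 higher and 4 lower (median −0.05), with Cd274 4.46-fold higher and Ltc4s 4.46-fold lower. The markers that define neutrophils were higher in 30 of 35 (median 1.46), those of monocytes had a median of 0.93 (0.80 with genes at 0 counts set to their bound) and those of NK cells 2.92 (2.16 at the bound), and mitochondrial genome genes were lower in 12 of 13 (median −0.90).

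Lower in TAC neutrophils were Hspa1b (15.3-fold), Pla2g2d (11.3-fold), Fam71a (10.2-fold), Hspa1a (9.13-fold), Igf1 (7.22-fold), Dnajb1 (7.20-fold), Chp2 (7.03-fold), Nav1 (6.77-fold), Cyr61 (6.67-fold) and Lrp6 (6.49-fold). Resident macrophage genes were lower as well (21 of 22, median −1.81), and 91.4% of sham but 42.2% of TAC neutrophil barcodes carried over 20 C1q UMIs per 10000, with 5 and 166 barcodes between 10 and 40. More macrophage RNA in sham barcodes lowers the CPM of neutrophil genes there and raises that of macrophage genes. How far it contributes to the higher granule genes and the lower genes of TAC neutrophils was not tested. The median log2 ratio over all measured genes was −0.36 in this class. Median-of-ratios scaling differed from CPM by −0.32, so a list near 0 lay above most genes, and the median of aged and SiglecF genes was 0.27 relative to that shift. At 1000 UMIs Il1b was detected in 66.7% of sham and 88.2% of TAC neutrophils, Cxcr4, which marks aged neutrophils, in 18.4% and 17.5%, and Siglecf in 0 of 174 (up to 1.72%) and 0.940%, the last 2 within the counting intervals. Fibroblast background was 3.30% and 6.48% for Il1b, at most 0.943% for Cxcr4 and 0% for Siglecf, and unthinned shares were 96.0% and 95.5%, 76.4% and 65.9%, and 6.32% and 4.53%. In macrophages, whose RNA these barcodes carried, Il1b was detected at 1000 UMIs in 12.7% and 23.9%. Sham neutrophils lay mostly in cluster 16 (153 sham and 13 TAC cells) and TAC neutrophils in clusters 4, 10 and 17. Cluster 17, led by the granule genes Ngp, Camp and Ltf, held 6 sham and 138 TAC cells. A different mix of neutrophils is therefore not separated from differences within them. S100a8 was at 13388 CPM in sham and 55042 CPM in TAC neutrophils. The Il1b difference of 21.5 points went to 1.94 without C1q-rich barcodes and −0.507 unthinned.

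T-like cells of the TAC library were higher in cytotoxic, cell cycle and interferon-inducible genes and lower in genes of naive T cells. Of 23 cytotoxic effector genes, 18 were higher and 0 lower (median 2.23, percentile 100), with granzyme genes Gzmb 39.97-fold (32.7 to 49.3) and Gzma 32.3-fold (28.1 to 37.2) higher. All 42 measured cell cycle genes were at least 1.5-fold higher (median 1.75), with Cdc20, a mitotic activator, 11.7-fold. Of 14 naive T cell genes, 13 were lower and 0 higher (median −1.28), with Tdrp 5.92-fold and Igfbp4 3.98-fold lower. Th17 and gamma-delta T genes had 9 of 13 lower and 1 higher (median −1.18), with Cd163l1 4.03-fold lower. Their median went to −0.13 with cells weighted equally. With cells thinned to 1000 UMIs it went to 0.24, over only 4 members that were still measured. Finer clustering (resolution 2) split the class largely by library, with 8 sham and 263 TAC cells in a cluster led by Gzmb and Ccl5 and 144 and 35 in a cluster with Tcf7, Ccr7 and Lef1, so a different mix of T cells is not separated from differences within T cells.

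Interferon-stimulated genes had 30 of 33 higher and 0 lower in T cells (median 1.69), and immediate-early and heat-shock genes 27 of 31 lower and 1 higher (median −1.29). Saa3 had 0 sham UMIs and was at least 508-fold higher in TAC, followed by Gbp2b (124-fold), Gbp2 (27.9-fold), Ifit2 (26.7-fold), Ly6a (26.5-fold), Il18bp (23.6-fold) and Iigp1 (19.7-fold). The histone genes Hist1h3c (32.3-fold), Hist1h2ab (22.2-fold) and Hist1h1b (21.5-fold) were higher too and are uncertain as members of a family of near-identical copies. Lower were Hspa1b (18.6-fold), Fam71a (13.03-fold), Hspa1a (10.3-fold), Pla2g2d (8.94-fold), Hspb1 (7.24-fold), Dnajb1 (6.19-fold), the co-chaperone gene Bag3 (5.41-fold), the transcription factor gene Klf4 (5.24-fold), Nav1 (5.09-fold) and Rnf150 (4.84-fold). T cell activation and inhibitory receptor genes had 11 of 23 higher and 5 lower (median 0.53), with Tnfrsf4, the costimulatory receptor OX40, 78.9-fold higher (14.02 to 3132, from 1 sham UMI). With cells thinned to 1000 UMIs the median of that list was 0.03, over only 11 members still measured, 2 higher and 4 lower. Regulatory T cell genes had 5 of 13 higher and 4 lower (median 0.35), with Il1rl1, the receptor of interleukin-33, 5.93-fold lower. Macrophage transcripts were abundant in these barcodes: 94.1% of sham and 70.9% of TAC T cell barcodes carried over 20 C1q UMIs per 10000, with 6 and 16 barcodes between 10 and 40. Resident macrophage genes had a median of −1.43 in them and mitochondrial genome genes −0.79. Markers of other cells went both ways. Those of neutrophils were higher in 26 of 32 (median 1.80), of monocytes in 22 of 31 (1.46) and of NK cells in 20 of 26 (1.78). B cell markers had 15 of 24 lower and 4 higher (−1.24), macrophage markers 26 of 48 and 9 (−0.70), and endothelial markers 9 of 19 and 5 (−0.58). The T cell markers themselves had 29 of 59 higher and 15 lower (0.56).

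At 1000 UMIs per cell Gzmb was detected in 3.29% (1.08 to 7.51) of sham and 45.9% (40.2 to 51.8) of TAC T cells, and Ifng, which encodes interferon-gamma, in 2.63% (0.722 to 6.60) and 18.2% (14.01 to 23.1). Cd8a was detected in 2.63% and 10.5%, Mki67 in 1.97% and 9.12%, and the inhibitory receptor gene Pdcd1 in 0% (up to 1.97%) and 3.04%. Differences were within the counting intervals for Trdc, a gamma-delta receptor constant gene (6.58% and 2.70%), Cd4 (0% and 1.35%), Ctla4 (1.32% and 2.03%), Il17a (1.32% and 1.35%) and Foxp3 (0% in both, up to 1.97% and 1.01%). Fibroblast background was at most 0.472% for these genes, but Mki67 was detected in 3.62% and 4.90% of macrophages, whose RNA these barcodes carried. Thinning matches total UMIs and not T cell UMIs. The T cell gene Cd3e was at 58.7 CPM in sham and 141 CPM in TAC T cells. How far macrophage RNA contributes to these differences was not tested. Unthinned shares were 7.24% and 68.9% for Gzmb, 15.1% and 47.0% for Ifng, 30.3% and 65.9% for Cd8a, 11.2% and 35.1% for Mki67, 7.89% and 25.3% for Pdcd1, and 15.1% and 4.05% for Trdc. They were 12.5% and 11.1% for Cd4, 7.24% and 27.7% for Ctla4, 3.95% and 2.03% for Il17a, and 0.658% and 0.676% for Foxp3. T cells had a median of 15850 UMIs in sham and 21460 in TAC.

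NK-like cells had a similar difference in Gzmb, detected in 18.9% (9.44 to 32.0) of 53 sham and 54.1% (42.1 to 65.7) of 74 TAC cells at 1000 UMIs. Ifng was detected in 17.0% and 28.4% and Mki67 in 5.66% and 14.9% of NK cells, both within the counting intervals. Unthinned shares were 58.5% and 93.2% for Gzmb, 67.9% and 78.4% for Ifng and 11.3% and 40.5% for Mki67. Of B cells, Ighd, the receptor isotype of mature naive B cells, was detected in 13.3% and 21.8%, Mki67 in 0.633% and 1.82%, and Cd5 in 0 of 158 (up to 1.90%) and 0 of 55 (up to 5.45%), all within the counting intervals. Unthinned B cell shares were 84.8% and 81.8% for Ighd, 6.96% and 18.2% for Mki67 and 0.633% and 0% for Cd5. Fibroblast background was 0% for Ighd, Cd5, Mki67 and Ifng and at most 0.472% for Gzmb. Macrophage RNA is not covered by that background, and in macrophages Mki67 was detected in 3.62% and 4.90%, above both B cell shares. C1q-rich barcodes were 98.7% of sham and 70.9% of TAC B cells, and 94.3% and 50% of NK cells. Between 10 and 40 C1q UMIs per 10000 lay 0 and 5 B cell barcodes and 0 and 4 NK cell barcodes.

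In monocytes, Ly6c2, a surface antigen of classical monocytes, was detected at 1000 UMIs in 32.8% (21.8 to 45.4) of 67 sham and 56.1% (50.7 to 61.3) of 353 TAC cells. Differences in Ccr2 (35.8% and 36.5%) and Mki67 (1.49% and 0.850%) were within the counting intervals. Ace, a gene of non-classical monocytes, was detected in 7.46% and 7.65%, below the 18.4% and 23.9% of fibroblasts. Background in fibroblasts for Ly6c2, Ccr2 and Mki67 was at most 1.62%. Macrophages had Ccr2 in 4.24% and 6.40% and Mki67 in 3.62% and 4.90%. Unthinned shares were 71.6% and 80.2% for Ly6c2, 80.6% and 82.4% for Ccr2, 25.4% and 39.1% for Ace and 5.97% and 12.2% for Mki67. C1q-rich barcodes were 52.2% of sham and 38.5% of TAC monocytes, with 4 and 39 barcodes between 10 and 40, and without them, in 32 sham and 217 TAC cells, the Ly6c2 difference of 23.3 points went to 2.84, the Ccr2 difference to −14.3 and the Ace difference to 10.6.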

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

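The mitochondrial limit of 25%, leaving out C1q-rich barcodes and the earlier naming rules were chosen after seeing the data, as was the set of lists followed in each class. The other alternatives were fixed in advance. No paired analysis was possible because each group is 1 library. Separate GEM wells were not run, since all barcodes carry the same suffix. The stricter filter gave no list or gene values, because it left 119 sham cells. Shares are log2 ratios of TAC to sham, lists are median log2 ratios, and detection is in percentage points, TAC minus sham. Where a value moved, the cause was not tested.

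All the results followed stayed within their intervals with 2 UMIs added (34), with member minimums of 5 (34) or 100 UMIs (34), with median-of-ratios scaling for lists (34), with doublets kept (43) and with immune classes only (7). Doublets kept is no test, since 4 cells were removed.

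All macrophages stayed in the total when C1q-rich barcodes were left out, and made up 82.7% of sham and 60.3% of TAC cells. With C1q-rich barcodes left out, shares were 2.55 for B cells (reversed from −1.95, with 2 sham and 16 TAC cells left), 3.17 for NK cells (3 and 37 cells), 2.80 for T cells (9 and 86), −1.48 for dendritic cells, 1.93 for endothelial cells and 5.04 for neutrophils (15 and 676). Detection was 10.6 for Ace, −14.3 for Ccr2 and 2.84 for Ly6c2 in monocytes and 1.94 for Il1b in neutrophils. The inflammatory median in fibroblasts was 0.87. The other 10 followed results kept their values within the intervals, and T, B and NK cells had too few sham cells left for detection values.

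With the stricter filter (500 genes and 5% mitochondrial UMIs together), shares were −0.49 for T cells and 0.28 for macrophages, both reversed. They were −1.48 for B cells, 1.04 for NK cells, −3.55 for dendritic cells, 1.06 for endothelial cells, −0.87 for fibroblasts, 1.09 for monocytes and 4.58 for neutrophils (1 sham cell). With a mitochondrial limit of 25%, shares were 0.87 for T cells, −1.78 for dendritic cells, 0.34 for endothelial cells, 0.22 for fibroblasts, −0.56 for macrophages and 2.69 for monocytes. In that setting the Th17 and gamma-delta median in T cells was −1.52 and the cell cycle median in macrophages 1.20, and 35 followed results stayed within their intervals.

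With each library clustered alone, the monocyte share reversed to −0.87, the dendritic cell share was −0.10 and the macrophage share −0.27, and 6 shares stayed within their intervals. With resolution 2 the dendritic cell share was −0.42, because cells led by Mmp12 and Cd209a (186 sham, 19 TAC) fell outside the class, and 42 results stayed. With the 50% naming limit the macrophage medians were 0.35 for cell cycle and 0.16 for oxidative phosphorylation, and 41 results stayed.

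With naming by correlation the dendritic cell share reversed to 1.62 and the macrophage cell cycle median to −1.40. The macrophage share was −1.44, the monocyte share 2.47, and the macrophage medians were 0.090 for inflammatory genes and −0.67 for resident genes. With naming by 30 genes the dendritic cell share was −2.86, the macrophage share −0.27, and the macrophage medians were 1.61 for MHC class II, 0.20 for cell cycle and 0.15 for oxidative phosphorylation.

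With cells weighted equally the Th17 and gamma-delta median in T cells was −0.13, and 33 results stayed. With cells thinned to 1000 UMIs that median reversed to 0.24, and the T cell cycle median was 1.22. These rest on 4 of 13 and 12 of 42 members, so they compare a different set of genes. The endothelial medians were −0.42 for MHC class II and 2.30 for interferon-stimulated genes.

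Without thinning, detection in T cells was −1.35 for Cd4, 35.6 for Cd8a, 20.5 for Ctla4, 61.7 for Gzmb, 31.8 for Ifng, 24.0 for Mki67, 17.4 for Pdcd1 and −11.1 for Trdc. In macrophages it was 1.5 for Arg1, 12.0 for Ccr2, −20.3 for Folr2, 28.0 for Il1b, −35.4 for Lyve1, 12.7 for Mki67, 16.8 for Spp1 and −11.4 for Timd4. In monocytes it was 13.7 for Ace, 8.53 for Ly6c2 and 6.21 for Mki67, in B cells −2.99 for Ighd and 11.2 for Mki67, and in NK cells 29.2 for Mki67. In neutrophils it was −10.5 for Cxcr4, −0.507 for Il1b (reversed) and −1.79 for Siglecf. Deeper cells detect more genes by construction, so the unthinned values mix depth with expression.

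With cells thinned to 2000 UMIs, detection was 20.4 for Cd8a, 6.77 for Ctla4 and 50.1 for Gzmb in T cells and 10.5 for Il1b in neutrophils. In macrophages it was 3.61 for Ccr2, −31.7 for Folr2, 13.5 for Il1b, −32.1 for Lyve1, 3.68 for Mki67, 6.97 for Spp1 and −5.08 for Timd4.

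Of 80 named gene values, 0 reversed. Those outside their counting interval numbered 47 with thinning, 22 with cells weighted equally, 14 with median-of-ratios scaling, 10 with a mitochondrial limit of 25%, 2 at resolution 2 and 1 with doublets kept. They numbered 15, 14 and 11 under the naming rules by 50%, correlation and 30 genes, and 4 of 20 without C1q-rich barcodes. Cell number limits the smaller classes (67 sham monocytes, 53 sham NK cells, 55 TAC B cells), and UMIs per cell limit what detection at 1000 UMIs can show of weakly expressed genes.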

Other observations

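Of the tests below, those of free RNA, random pairing, depth, macrophage RNA in fibroblasts and doublets of named classes were chosen only after the result was seen. In TAC macrophages, chemokine receptor and adhesion genes had 7 of 19 higher and 3 lower (median log2 ratio 0.20), with S1pr1, a tissue egress receptor, 4.09-fold lower. Growth factor and repair ligand genes had 6 of 19 higher and 6 lower (median 0.06), with Nrg1 5.98-fold higher and Hbegf, an epidermal growth factor receptor ligand, 2.98-fold lower. Receptors for angiotensin, catecholamines and steroids had 1 of 8 higher and 4 lower (median −0.61), with Ednrb, an endothelin receptor, 5.85-fold lower. B cell activation genes had a median of 0.21 in macrophages, immunoglobulin heavy chain genes −0.25 and sex-linked genes −0.61.

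In TAC T cells, Cxcr3, the receptor of Cxcl9, was 3.34-fold higher and Ccr7, a lymph node homing receptor, 3.93-fold lower, within a list whose median was 0.65. In fibroblasts, Spp1 was 10.4-fold and Fn1, which encodes fibronectin, 2.997-fold higher and Lpl, lipoprotein lipase, 3.11-fold lower. Thbs1, an activator of transforming growth factor beta, was 8.73-fold higher in endothelial cells. Mki67 was 4.72-fold lower there, within cell cycle genes of which 11 of 28 were lower and 2 higher. Macrophages carry Mki67 too, and C1q-rich barcodes were 37.0% of sham and 8.41% of TAC endothelial cells. How far macrophage RNA contributes to the lower cell cycle genes was not tested.

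C1q transcripts of macrophages were found in many barcodes of lymphocytes and neutrophils, more often in the sham library. Free RNA spread evenly would load all classes alike, but C1q-rich barcodes were 80.5 points more frequent in sham T cells than in sham fibroblasts. Barcodes picked by the T cell genes Cd3d, Cd3e and Cd3g were C1q-rich 79.8 points more often than barcodes picked by fibroblast genes. That argues against random pairing with macrophages, but the rules for picking differed. At least 3 UMIs were asked for T cells, which favours deep barcodes. At least 20 UMIs per 10000 were asked for fibroblasts, which favours undiluted barcodes. Such rules push the shares apart, so part of the difference may come from picking. A macrophage and a T cell together in a barcode stay open: T cell markers in C1q-rich TAC T cells stood at 0.372 of their CPM in other T cells, but with other macrophage markers at 66.6% (59.3 to 73.7) of the macrophage level any source of that RNA would dilute them as much. C1q-rich TAC barcodes were also deeper, with medians of 24703 against 8745 UMIs in T cells and 27595 against 13070 in NK cells. In TAC neutrophils the medians were 17904 against 4550.5. TAC macrophages had a median of 14196, so the excess was of the order of a macrophage, but its source was not tested. The cells were sorted on CD45, which macrophages and T cells both carry, and no biological explanation was tested.

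Interferon-stimulated genes such as Gbp2 and Ifi44 were higher in TAC in all 5 compared classes. With cells thinned to 1000 UMIs, the lowest median over the classes was 1.74, with 21 of 33 members still measured in T cells. CPM is already scaled to the class total, so thinning mainly gives cells equal weight. It shows that the difference does not rest on the deepest cells, and it cannot decide on depth. Macrophage RNA is argued against in fibroblasts and endothelial cells by medians of 2.13 (1.66 to 2.73) and 1.88 (1.66 to 2.20) without C1q-rich barcodes. Macrophage RNA stays open in neutrophils and T cells, where the medians of 2.74 and 1.59 rest on 15 and 9 sham cells. In macrophages with 5 to 8% mitochondrial UMIs in both libraries the interferon median was 1.72 (1.21 to 2.13), and the immediate-early and heat-shock median −0.61. That argues against the mitochondrial share of the kept macrophages as the source. The match is partial, with median shares of 7.09% in sham and 6.04% in TAC within the band. Barcodes removed by the filter are not covered. Interferon released in the TAC heart and a difference between the libraries other than the operation, such as an infection or the handling of the hearts, both stay open and were not tested.

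The cells left unnamed were deep, with median depths of 38576 UMIs in sham and 45320 in TAC, and carried Lyz2 at 14600 and 16414 CPM, Gpnmb at 407 and 730 CPM and Hmga2 at 143 and 118 CPM. Doublets of named classes are argued against by 80 genes in sham that exceeded 3 times their highest CPM in any named class. Barcodes swapped between libraries are argued against by 0 of 177 sham barcodes (0%, up to 1.69%) found among the TAC barcodes, against 0.225% of other kept sham barcodes. Cells of 1 shared source added to both libraries stay open, since the interferon median in these cells was 1.26 (0.48 to 1.98), which is too wide an interval to exclude it. No biological explanation was tested for these cells.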
